A study of Homo sapiens with 6 samples.

How the data were processed

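Total RNA of LNCaP cells was measured on 6 Illumina HT-12 v4 bead arrays. Per the labels, 2 arrays held control cells and 2 arrays each held cells exposed to 30 µM MK591 for 8 or 16 hours, after 48 hours of growth in medium with 10% serum. All 6 arrays were used, and 0 columns of values were left without a sample. The labels give the arrays of each group replicate numbers and do not say whether these pair arrays across groups. With group means removed, arrays of the same number correlated with r = -0.00907, 0.0336 and 5.6e-04 between the groups, which showed no pairing. The model, fixed before the data were examined, held no replicate term.

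The deposited signal values are intensities per the file headers, the mean bead signal of each of 47231 probes, neither background corrected nor normalized by the authors. Each comes with a deposited detection p-value per the file headers, the share of the negative control probes at or above the signal, in steps that imply 770 negative controls. The authors' processed values are on a log2 scale as deposited and hold the same distribution on all arrays (median 7.04), as quantile normalization leaves them; the labels do not name the method. The bright end of the signals, which 1% of probes exceeded, lay at 9081 and 7485 on the control arrays, 6942 and 6895 at 8 hours, and 5914 and 5118 at 16 hours.

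Signals were background corrected with a normal-exponential model whose background was inferred from the detection p, raised by an offset of 16, quantile normalized and taken to log2 (neqc of limma 3.58.1 in R 4.3.3). A probe passed if its detection p was under 0.01 on both arrays of at least 1 group, as 15884 probes did. Gene symbols came from a probe annotation that named 1 gene for 30113 probes and several for 8, and 17110 probes without a symbol were not used in the comparisons. Of the passing probes 12768 had 1 symbol. Each gene was represented by its brightest passing probe, which gave 9756 genes, 2454 of them with over 1 passing probe and 7966 detected on all 6 arrays. Members of the gene lists, and a gene of the set fixed in advance, that had no named probe were not analysed here.

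Groups were compared with limma (lmFit, contrasts.fit and eBayes) on all 6 arrays with group as the only term, in 3 comparisons: 8 hours versus control, 16 hours versus control, and 16 versus 8 hours. There were 3 residual degrees of freedom, and the prior had 4.42 with a residual SD of 0.129 log2 units. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called higher or lower. Where no array of a group detected the probe, the change is given as a bound: the mean of the brighter group against, on each array of the dimmer group, the higher of the probe's own signal and the lowest signal among detected probes. Figures were drawn with matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15.

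Of 28 gene lists, 27 had at least 3 measured members and were tested with limma's camera at a preset correlation of 0.01, over 81 tests adjusted together. The lists were MYC targets of ribosome biogenesis and growth, androgen-regulated genes, ATF4 and integrated stress response targets, ER chaperones and quality control, cholesterol synthesis and uptake, fatty acid synthesis, PPAR targets of fatty acid oxidation, NRF2 antioxidant targets, p53 targets, DNA replication, mitosis, the BCL2 family and death receptors, heat shock, immediate early and MAPK response, the eicosanoid pathway, autophagy and lysosome, hypoxia and glycolysis, metallothioneins and zinc response, NF-kappaB and cytokine response, interferon response, retinoid and bile acid type receptor targets, the mitochondrial respiratory chain, cytosolic ribosomal proteins, and markers of luminal, neuroendocrine, basal, stromal, and leukocyte and endothelial cells. Of 508 measured list genes, 11 stood in over 1 list, such as KLK3 in the androgen and luminal lists and SESN2 in the ATF4 and p53 lists. For some lists not called, the median, the mean and the direction of camera differed in sign. Camera was also run with the correlation estimated for each list, and the self-contained test fry was run. With an estimated correlation camera rests on the 3 residual degrees of freedom and has little power over 81 tests. A list not called by it is therefore not shown to owe its call to correlated members.

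The named genes were the 10 with the largest fold in each direction against control (5 between the treatment times) among called genes whose arrays did not overlap between groups, up to 4 members of each list with the smallest adjusted p, and MYC, ALOX5, ALOX5AP, KLK3, CDKN1A, CCND1 and MCL1 whatever their test. The rule names 121, 118 and 114 genes in the 3 comparisons, of which the text gives some. Values of further genes, listed here for the comparison they fall outside the rule in, were chosen after their values were seen: CCL2, HSPA5, SLC30A1 and STC2 at 8 hours, CCN1, DDIT3, DUSP4, E2F2, EDEM1, HSPA5, LTA4H and STC2 at 16 hours, and ATF3, MAT2A and SLC30A1 between the times, beside the gene families of the closing observations. This rule, the lists, the tests of genes and lists and the alternatives were fixed before the data were examined, except 1 alternative, the split of the control arrays. The gene families and the tests of explanations in the closing observations were chosen after the results were seen, apart from the test of decay factors.

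The changes at 8 and 16 hours share the control arrays, so their correlation was set beside 100 simulations. These drew all 6 arrays, controls included, without group differences, and set both times against the same simulated controls. In a separate run of 100 simulations of this kind, the highest number of genes called at 16 hours was 2 and the median 0. This follows from simulating no difference between groups, so it does not bear on the cause of the 5933 calls in the data. Recovery was tested on simulated data with 50 genes changed by each fold: at 8 hours 0% of 1.25-fold, 16% of 1.5-fold, 90% of 2-fold and 100% of 4-fold changes were called, and at 16 hours 0%, 30%, 96% and 98%. Of unchanged genes, 4 and 6 of 9556 were called against control and 0 of 9756 between the times. Few genes were changed in this simulation, so its adjusted threshold was stricter than in the data, and small changes may be recovered more often there. The alternatives were no background correction, median scaling in place of quantile normalization, the authors' processed values, 3 other detection filters, the mean of a gene's probes, a replicate block, an intensity trend with robust variance, array weights, a fit of only the arrays compared, a 2-fold minimum, and leaving out each array in turn. For the correlation of the 8 and 16 hour changes, setting each time against a control array of its own was added after seeing the data.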

Results

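Gene expression was measured in LNCaP cells, a human prostate cancer cell line whose growth depends on androgen signalling, with and without MK591. MK591 (quiflapon) inhibits the 5-lipoxygenase activating protein, the product of ALOX5AP, which hands arachidonic acid to 5-lipoxygenase (ALOX5) for the synthesis of leukotrienes. The cells had grown for 48 hours after plating and were then exposed to 30 µM MK591 for 8 or 16 hours. Each of the 3 groups (control, 8 hours and 16 hours) was represented by 2 Illumina HT-12 v4 bead arrays, 6 in all. Mean probe signal was 488 and 416 on the control arrays, 427 and 418 at 8 hours, and 382 and 342 at 16 hours. Between 14255 and 15806 of the 47231 probes had a detection p below 0.01 on an array, and 9756 genes were tested. Arrays of one group correlated across genes with r between 0.991 and 0.994, against 0.908 to 0.912 between control and 8 hours, 0.897 to 0.901 between control and 16 hours and 0.954 to 0.956 between the treatment times. Genes are not independent replicates, so these values only describe the arrays. The labels do not say whether the arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. The labels also name no vehicle and no harvest time for the control.

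The first comparison asked which transcripts had changed after 8 hours of MK591. At that time the lists of the integrated stress response, endoplasmic reticulum (ER) quality control, metallothioneins and cytokines were called higher in LNCaP cells, and those of DNA replication, mitosis and androgen-regulated genes lower. With an estimated correlation 0 lists were called (adjusted p = 0.0837 to 0.161 with an estimated correlation for these lists). That test has little power with 3 residual degrees of freedom, here and in the other comparisons, so it cannot decide whether correlated members explain the calls. DDIT3, a transcription factor of the stress response that promotes cell death, rose by 4.68 ± 0.14 on the log2 scale (SE, 25.7-fold; limma adjusted p = 1.7e-06). CCL20, a chemokine that attracts lymphocytes, was at least 43.7-fold higher (limma adjusted p = 5.4e-07). MYC, a transcription factor that drives growth and ribosome production, fell by 2.93 ± 0.12 on the log2 scale (7.60-fold; limma adjusted p = 7.4e-06), and KLK3, which encodes prostate-specific antigen, fell by 2.80 ± 0.17 (6.94-fold; limma adjusted p = 2.3e-05). Of the 9756 genes tested with limma, 2921 were higher and 2723 lower at 8 hours (57.9% in all), of which 924 and 772 changed at least 2-fold and 147 and 78 at least 4-fold. For the genes named here by their fold, in each comparison, both arrays of one group lay beyond both arrays of the other.

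All 38 measured members of the list of ATF4 and integrated stress response targets, the genes switched on when cells slow protein synthesis under stress, were higher at 8 hours (0 lower, 0 not called; 38 higher when adjusted over the list alone). Their median log2 change was 1.61, and limma's camera test called the list higher (adjusted p = 6.7e-15; adjusted p = 0.123 with an estimated correlation). ATF3, a stress-induced transcription factor, rose by 4.34 ± 0.12 on the log2 scale, CTH, an enzyme that makes cysteine, by 4.34 ± 0.18, and SLC3A2, the heavy chain of amino acid transporters, by 3.89 ± 0.11. SESN2, a regulator of the nutrient-sensing kinase mTORC1 that was detected on no control array, was at least 8.02-fold higher. Of 25 measured genes of ER chaperones and ER quality control, 21 were higher, 0 lower and 4 not called (21 higher when adjusted over the list alone). ER genes had a median log2 change of 0.78 (camera adjusted p = 4.7e-07; adjusted p = 0.123 with an estimated correlation). DNAJB9, a co-chaperone of the ER lumen, rose by 4.26 ± 0.10, XBP1, a transcription factor of the unfolded protein response, by 2.67 ± 0.10, and HSPA5, the main chaperone of the ER, by 1.40 ± 0.12.

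All 8 measured genes of the metallothionein and zinc response list, which bind or export zinc, were higher at 8 hours (0 lower, 0 not called; 8 higher when adjusted over the list alone). The median change was 9.95-fold (camera adjusted p = 4.7e-07; adjusted p = 0.161 with an estimated correlation). MT1X rose by 4.29 ± 0.10 on the log2 scale and MT1G by 3.44 ± 0.11, while the plasma membrane zinc exporter SLC30A1 rose by 4.04 ± 0.15. SLC30A2, another zinc transporter and no member of the list, was at least 22.3-fold higher. The metallothionein genes are near-identical copies, so the share of each single copy is uncertain. Of 14 measured genes of the NF-kappaB and cytokine response, 13 were higher, 0 lower and 1 not called (13 higher when adjusted over the list alone). The median log2 change was 1.54, or 1.33 with the 9 genes undetected on the arrays of a group set at their bounds (camera adjusted p = 1.75e-06; adjusted p = 0.123 with an estimated correlation). Genes undetected on the control arrays passed the detection filter only because a treated group detected them. Such genes could hardly be called lower, so the filter favours rises in this list. At the preset correlation the cytokine list stayed called among genes detected on every array. TNF, an inflammatory cytokine, was at least 11.4-fold higher, RELB, a subunit of NF-kappaB, at least 5.14-fold, and the chemokine CXCL8 at least 26.0-fold on the probe used, although another CXCL8 probe was detected in control.

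Of 31 measured genes of DNA replication and the entry into S phase, 29 were lower, 0 higher and 2 not called (29 lower when adjusted over the list alone). Replication genes had a median log2 change of -1.59 (camera adjusted p = 2.7e-13; adjusted p = 0.0837 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell by 2.64 ± 0.13 on the log2 scale, PCNA, the sliding clamp of DNA polymerase, by 2.58 ± 0.13, and CDC25A, a phosphatase that activates cyclin-dependent kinases, by 2.36 ± 0.10. Of 36 measured mitosis genes, 34 were lower, 0 higher and 2 not called (34 lower when adjusted over the list alone). Mitosis genes had a median log2 change of -1.28, or -1.21 with 1 undetected gene at its bound (camera adjusted p = 1.2e-13; adjusted p = 0.0837 with an estimated correlation). KIF20A, a kinesin of cell division, fell by 2.19 ± 0.10 and CDK1, the kinase that starts mitosis, by 2.16 ± 0.14.

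Among 25 measured androgen-regulated genes, 16 were lower, 2 higher and 7 not called (17 lower and 2 higher when adjusted over the list alone). Androgen-regulated genes had a median log2 change of -0.55, or -0.51 with 3 undetected genes at their bounds (camera adjusted p = 0.00138; adjusted p = 0.161 with an estimated correlation). TMPRSS2, a membrane serine protease of prostate epithelium, fell by 2.74 ± 0.12 on the log2 scale, whereas ACP3, prostatic acid phosphatase, rose by 1.41 ± 0.13. Of 46 MYC targets of ribosome biogenesis and growth, 23 were lower, 5 higher and 18 not called (23 lower and 6 higher when adjusted over the list alone). MYC targets had a median log2 change of -0.35 (camera adjusted p = 0.0270; adjusted p = 0.201 with an estimated correlation). PHB1, prohibitin of the inner mitochondrial membrane, fell by 2.28 ± 0.11, and RRP12, a factor of ribosome assembly, rose by 1.37 ± 0.14.

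Of 18 genes of cholesterol synthesis and uptake, 8 were lower, 3 higher and 7 not called (8 lower and 3 higher when adjusted over the list alone; median log2 change -0.36, camera adjusted p = 0.0388, adjusted p = 0.267 with an estimated correlation). INSIG1, which holds the sterol sensor in the ER, fell by 1.55 ± 0.11 and the sterol isomerase EBP by 1.59 ± 0.14, while SC5D, a sterol desaturase, rose by 1.73 ± 0.12. Of 27 genes of hypoxia and glycolysis, 16 were lower, 4 higher and 7 not called (16 lower and 4 higher when adjusted over the list alone; median log2 change -0.37, camera adjusted p = 0.0438, adjusted p = 0.243 with an estimated correlation). CA12, a carbonic anhydrase, fell by 1.53 ± 0.15 and LDHA, lactate dehydrogenase, by 0.81 ± 0.10. The call of cholesterol synthesis and uptake, 8 hours versus control, was lost without control replicate 2 (adjusted p = 0.0565), without 8 hour replicate 1 (0.0772), among genes detected on all 6 arrays (0.0598) and with a detection p under 0.05 (0.0513), over a range of 0.0112 to 0.0772 across the alternatives at the preset correlation. The call of hypoxia and glycolysis, 8 hours versus control, was lost without control replicate 2 (adjusted p = 0.0660) and without 8 hour replicate 1 (0.0642) or 2 (0.0528), over a range of 0.00700 to 0.0660.

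The other 17 lists were not called at 8 hours, though single members changed. Among 16 genes of fatty acid synthesis, 9 were lower and 3 higher (the same counts adjusted over the list alone; camera adjusted p = 0.0588), and the desaturase FADS2 fell by 1.88 ± 0.11 on the log2 scale. Of 9 genes of the eicosanoid pathway, which the target of MK591 belongs to, 7 were lower and 0 higher (the same adjusted over the list alone; camera adjusted p = 0.0548), among them MGST2, a glutathione transferase that can make leukotrienes, which fell by 1.27 ± 0.12. Of 18 heat shock genes, 9 were lower and 4 higher (the same adjusted over the list alone; camera adjusted p = 0.0599). HSPA1B, an inducible cytosolic chaperone, fell by 1.81 ± 0.10, and the small heat shock protein gene HSPB8 was at least 3.41-fold higher. Of 28 genes of autophagy and the lysosome, 13 were higher and 5 lower (the same adjusted over the list alone; camera adjusted p = 0.130), with rises of 2.01 ± 0.11 for SQSTM1, an autophagy receptor, and 1.93 ± 0.14 for MAP1LC3B, a protein of the autophagosome membrane. Of 17 antioxidant targets of NRF2, 9 were higher and 2 lower (the same adjusted over the list alone; camera adjusted p = 0.222), and HMOX1, heme oxygenase, rose by 1.93 ± 0.14. Of 21 p53 targets, 9 were higher and 5 lower (the same adjusted over the list alone; camera adjusted p = 0.343). GADD45A, a growth arrest gene, rose by 2.71 ± 0.17, and TP53INP1, a stress-induced p53 partner, fell by 1.40 ± 0.10.

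Of 18 genes of the BCL2 family and death receptors, 7 were higher and 3 lower (the same adjusted over the list alone; camera adjusted p = 0.485). PMAIP1, which promotes apoptosis, was at least 2.70-fold higher and BIK, another such gene, at least 3.64-fold lower. Of 19 immediate early and MAPK response genes, 9 were higher and 3 lower (9 and 4 adjusted over the list alone; camera adjusted p = 0.332), and DUSP1, a MAP kinase phosphatase, rose by 1.66 ± 0.11. Of 12 interferon response genes, 4 were higher and 3 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.793). IRF1, a transcription factor of that response, was at least 6.13-fold higher, and ISG15, a ubiquitin-like protein, fell by 1.23 ± 0.11. Of 14 genes of luminal prostate identity, 7 were lower and 3 higher (7 and 4 adjusted over the list alone; camera adjusted p = 0.224), and the homeobox factor HOXB13 fell by 1.85 ± 0.17. Among the remaining lists, 0 genes of the mitochondrial respiratory chain were higher and 4 of 24 lower (3 lower adjusted over the list alone; camera adjusted p = 0.343), and 2 cytosolic ribosomal proteins were higher and 1 of 24 lower (0 and 0 adjusted over the list alone; camera adjusted p = 0.980). Of 15 PPAR targets of fatty acid oxidation 2 were higher and 3 lower (2 and 2 adjusted over the list alone; camera adjusted p = 0.793), and of 6 retinoid and bile acid type receptor targets 2 were higher and 2 lower (the same adjusted over the list alone; camera adjusted p = 0.980).

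Markers of other cell types were few on these arrays. Of the neuroendocrine markers 3 genes were measured and 2 were lower at 8 hours (2 adjusted over the list alone; camera adjusted p = 0.503), of the stromal and mesenchymal markers 4 and 1 (1 adjusted over the list alone; camera adjusted p = 0.774), and of the basal epithelial markers 0. Of 3 measured leukocyte and endothelial markers 2 were higher and 0 lower (2 adjusted over the list alone; camera adjusted p = 0.241), among them VWF, von Willebrand factor of endothelium and platelets, at least 2.66-fold. Outside the lists, TM4SF1, a membrane protein of many carcinomas, fell by 3.81 ± 0.13 on the log2 scale, SLC16A10, an aromatic amino acid transporter, by 3.19 ± 0.16, and B4GALT5, a galactosyltransferase of glycosphingolipid synthesis, by 2.86 ± 0.15. CROT, which moves fatty acids out of peroxisomes as carnitine esters, was at least 5.56-fold lower. BEST1, a chloride channel, was at least 9.94-fold higher.

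**Figure D1:**
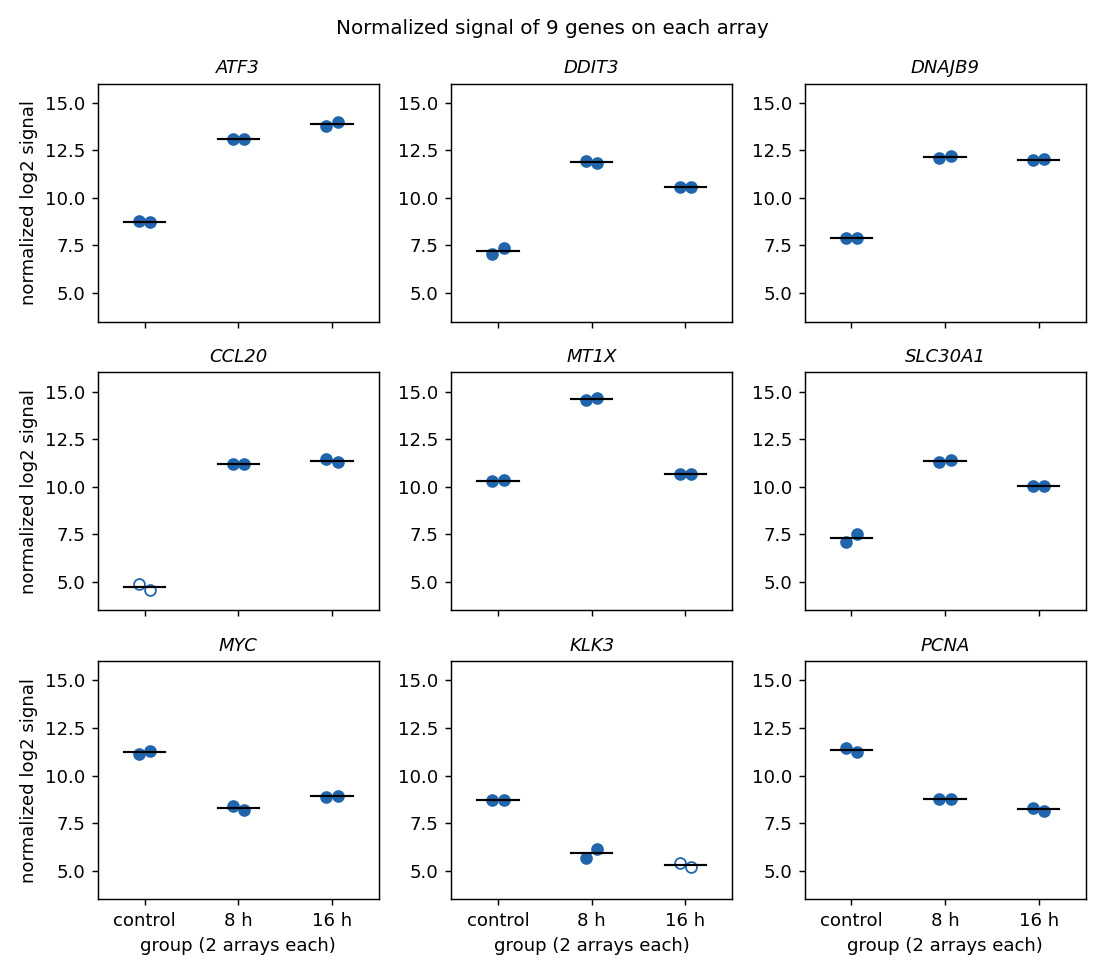
Normalized log2 signal (vertical axis) of 9 genes on each array of the control, 8 hour and 16 hour groups; points are arrays, horizontal lines are group means of 2 arrays, and hollow points mark groups in which no array detected the probe. ATF3, DDIT3, DNAJB9 and CCL20 lie above control at both times, MT1X lies high only at 8 hours on this axis (change of 4.29 at 8 hours and 0.36 at 16 hours), and MYC, KLK3 and PCNA lie below control at both times.

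The second comparison asked which transcripts differed from control after 16 hours. The lists of stress response, ER, cytokine and immediate early genes were called higher at that time, and those of mitosis, DNA replication, cholesterol and fatty acid synthesis, the eicosanoid pathway and androgen-regulated genes lower. Again 0 lists were called with an estimated correlation (adjusted p = 0.0837 to 0.243 with an estimated correlation for these lists). IRF1 was at least 24.9-fold higher (limma adjusted p = 6.6e-07) and CCL2, a chemokine that attracts monocytes, at least 29.7-fold (limma adjusted p = 2.2e-06). PRDX1, a peroxiredoxin that removes hydrogen peroxide, fell by 3.92 ± 0.14 on the log2 scale (15.2-fold; limma adjusted p = 4.0e-06), and MAT2A, which makes the methyl donor S-adenosylmethionine, by 3.29 ± 0.11 (9.77-fold; limma adjusted p = 3.3e-06). KLK3 was detected on no array at 16 hours and was at least 8.71-fold lower than in control (limma adjusted p = 9.1e-06). In all, 3202 of 9756 genes were higher and 2731 lower (60.8%), of which 1114 and 885 changed at least 2-fold and 187 and 96 at least 4-fold.

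Of the 38 stress response targets of ATF4, 32 were higher, 1 lower and 5 not called at 16 hours (34 higher and 1 lower when adjusted over the list alone). The ATF4 targets had a median log2 change of 1.41, or 1.35 with 3 undetected genes at their bounds (camera adjusted p = 1.98e-09; adjusted p = 0.161 with an estimated correlation). ATF3 rose by 5.13 ± 0.12 on the log2 scale, CTH by 3.97 ± 0.18, SLC3A2 by 3.70 ± 0.11 and DDIT3 by 3.36 ± 0.14. The member that fell was STC2, the secreted glycoprotein stanniocalcin 2, by 0.84 ± 0.14. Of the 25 ER genes, 20 were higher, 2 lower and 3 not called (20 higher and 2 lower when adjusted over the list alone). ER genes had a median log2 change of 0.70 (camera adjusted p = 3.4e-04; adjusted p = 0.149 with an estimated correlation). DNAJB9 rose by 4.12 ± 0.10 and XBP1 by 2.98 ± 0.10. The members that fell were HSPA5, by 0.62 ± 0.12, and EDEM1, which directs misfolded glycoproteins to degradation, by 0.33 ± 0.12, a call lost without either control array, either 8 hour array or 16 hour replicate 2 (limma adjusted p = 0.0535 to 0.227).

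Of the 14 NF-kappaB and cytokine genes, 12 were higher, 0 lower and 2 not called at 16 hours (13 higher when adjusted over the list alone). The cytokine genes had a median log2 change of 2.38, or 2.37 with 9 undetected genes at their bounds (camera adjusted p = 9.1e-07; adjusted p = 0.123 with an estimated correlation). CCL20 was at least 49.3-fold higher, TNF at least 17.4-fold and TNFAIP3, a ubiquitin-editing inhibitor of NF-kappaB, at least 8.84-fold. Of 19 immediate early and MAPK response genes, 14 were higher, 2 lower and 3 not called (14 higher and 2 lower when adjusted over the list alone). Immediate early genes had a median log2 change of 0.83, or 0.73 with 3 undetected genes at their bounds (camera adjusted p = 0.00383; adjusted p = 0.201 with an estimated correlation). The AP-1 subunits JUNB and JUN rose by 3.06 ± 0.18 and 2.68 ± 0.10, and CCN1, a matricellular protein, by 2.01 ± 0.14, while DUSP4, a MAP kinase phosphatase, fell by 0.77 ± 0.19.

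Mitosis genes were the list with the lowest median at 16 hours, where 33 of 36 were lower, 0 higher and 3 not called (34 lower when adjusted over the list alone). Mitosis genes had a median log2 change of -1.39 (camera adjusted p = 1.2e-13; adjusted p = 0.0837 with an estimated correlation). CCNA2, cyclin A, fell by 2.72 ± 0.12 on the log2 scale and UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, by 2.10 ± 0.11. Of 31 DNA replication genes, 26 were lower, 0 higher and 5 not called (27 lower and 1 higher when adjusted over the list alone). DNA replication genes had a median log2 change of -1.01 (camera adjusted p = 3.6e-08; adjusted p = 0.123 with an estimated correlation). PCNA fell by 3.12 ± 0.13 and RRM2 by 2.43 ± 0.13, whereas E2F2, a transcription factor of S phase entry, had a log2 change of -0.12 ± 0.11 (limma adjusted p = 0.35). Of 25 androgen-regulated genes, 13 were lower, 2 higher and 10 not called (13 lower and 2 higher when adjusted over the list alone). The androgen-regulated genes had a median log2 change of -0.36 (camera adjusted p = 0.00658; adjusted p = 0.199 with an estimated correlation). TMPRSS2 fell by 1.69 ± 0.12, TPD52, a protein of vesicle traffic, by 1.18 ± 0.11, and TRPM8, a cold-activated calcium channel, was at least 2.93-fold lower.

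Most measured genes of lipid synthesis were lower at 16 hours. Of 18 cholesterol genes, 13 were lower, 3 higher and 2 not called (14 lower and 3 higher when adjusted over the list alone). Cholesterol genes had a median log2 change of -0.43 (camera adjusted p = 0.0148; adjusted p = 0.243 with an estimated correlation). INSIG1 fell by 2.36 ± 0.11 on the log2 scale and ACAT2, which makes the precursor acetoacetyl-CoA, by 1.59 ± 0.12, while SC5D rose by 1.78 ± 0.12. Of 16 genes of fatty acid synthesis, 12 were lower, 2 higher and 2 not called (12 lower and 2 higher when adjusted over the list alone). Fatty acid synthesis genes had a median log2 change of -0.69 (camera adjusted p = 0.00812; adjusted p = 0.201 with an estimated correlation). The desaturases SCD and FADS2 fell by 1.79 ± 0.11 and 1.78 ± 0.11, and SREBF1, a transcription factor of lipid synthesis, by 1.19 ± 0.13. Of 9 eicosanoid pathway genes, 8 were lower, 0 higher and 1 not called (8 lower when adjusted over the list alone). The eicosanoid genes had a median log2 change of -0.92, or -0.62 with 2 undetected genes at their bounds (camera adjusted p = 0.00649; adjusted p = 0.201 with an estimated correlation). MGST2 fell by 1.06 ± 0.12, MGST3, another glutathione transferase, by 1.02 ± 0.10, and LTA4H, which makes leukotriene B4, by 0.55 ± 0.13. All 3 measured neuroendocrine markers were lower (0 higher, 0 not called; 3 lower when adjusted over the list alone). The neuroendocrine markers had a median log2 change of -1.25, or -0.73 with 1 undetected gene at its bound (camera adjusted p = 0.0271; adjusted p = 0.290 with an estimated correlation). TUBB3, a neuronal tubulin, fell by 1.25 ± 0.10, and ENO2, neuronal enolase and also a member of the glycolysis list, was at least 1.66-fold lower. Among 17 tubulin genes, a family chosen after the results were seen, 14 were lower and 2 higher at 16 hours (median log2 change -1.10). The fall of TUBB3 is therefore not particular to the neuroendocrine list. The call of the eicosanoid pathway was lost without a detection filter (median log2 change -0.07, adjusted p = 0.136) and with a detection p under 0.05 (median -0.55, adjusted p = 0.0549), over a range of 0.00346 to 0.136. The call of the neuroendocrine markers was lost without a detection filter (median log2 change 0.01, adjusted p = 0.550), over a range of 0.0235 to 0.550, and without 16 hour replicate 2 the falls of LTA4H and DUSP4 were not called (limma adjusted p = 0.0557 and 0.0703).

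The other 16 lists were not called at 16 hours, including the 8 metallothionein and zinc response genes, of which 3 were higher, 1 lower and 4 not called (3 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.385). SLC30A1 remained 2.73 ± 0.15 above control on the log2 scale (6.63-fold; limma adjusted p = 1.1e-05). Among genes outside the lists or in lists not called, PHB1 fell by 3.41 ± 0.11 on the log2 scale, MSMB, a secreted protein of prostate epithelium, was at least 5.59-fold lower, and DHRS3, a retinaldehyde reductase, rose by 2.46 ± 0.11. GABARAPL1, a protein of autophagosomes, rose by 2.02 ± 0.10, and BCL2L1, which protects cells from apoptosis, by 0.84 ± 0.11.

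**Figure D2:**
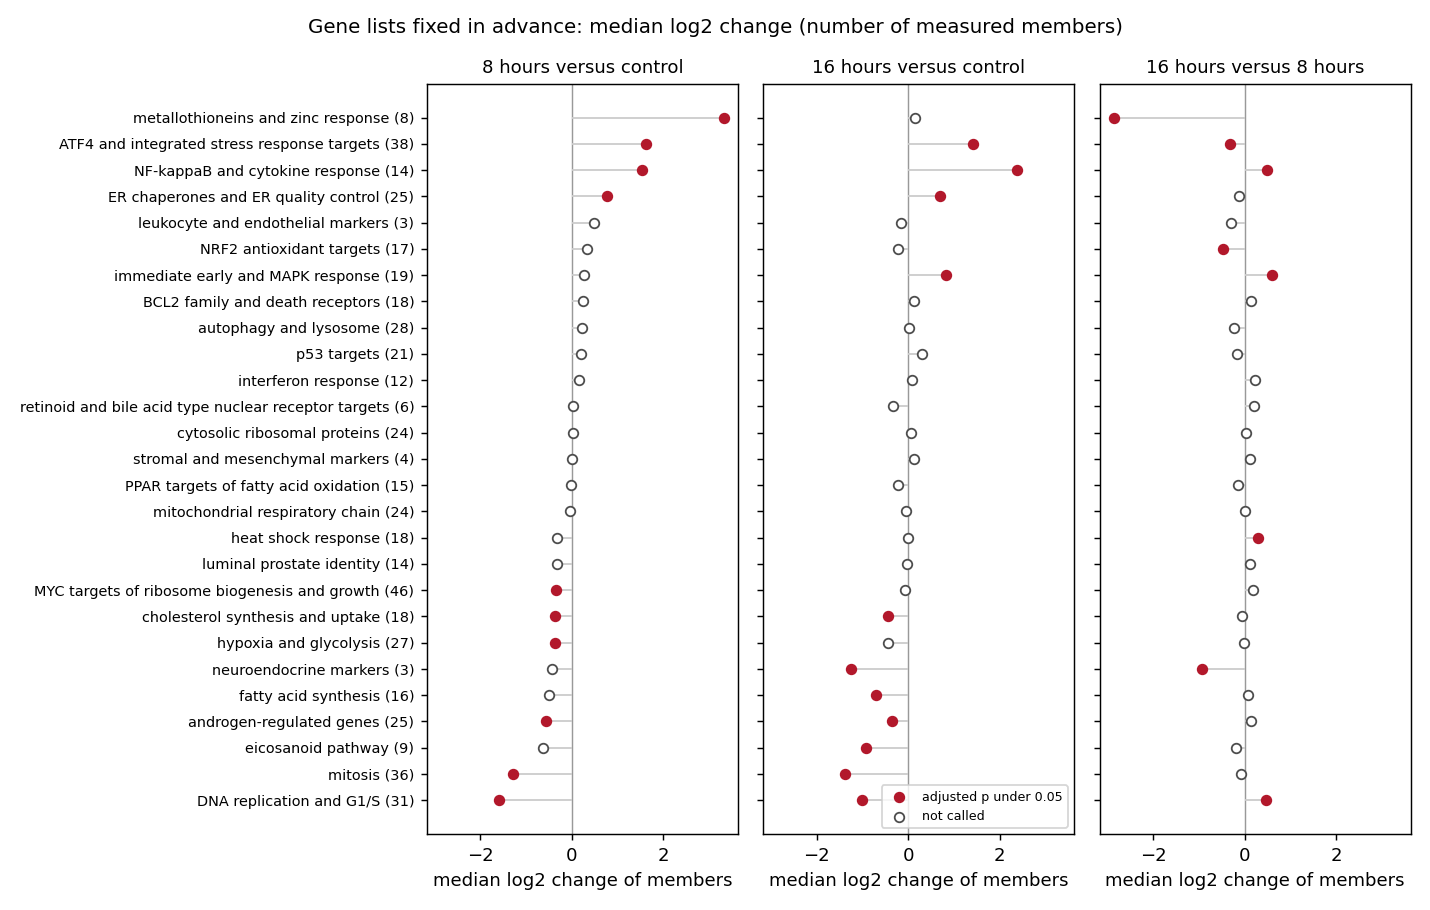
Median log2 change (horizontal axis) of the measured members of 27 gene lists in each of the 3 comparisons, with the number of measured members in brackets; filled points passed the camera test at an adjusted p under 0.05 and hollow points did not. The metallothionein and zinc response list has the highest median at 8 hours (3.31) and the lowest between 8 and 16 hours (-2.85), and DNA replication and mitosis have the lowest medians at 8 hours (-1.59 and -1.28).

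The third comparison set the treatment times against each other. All 8 metallothionein and zinc response genes, 16 of 38 ATF4 targets and 9 of 17 NRF2 targets were lower at 16 than at 8 hours, and these lists were called lower. The lists of DNA replication, the immediate early response, the cytokine response and the heat shock response were called higher, the last with 8 of 18 genes higher. With an estimated correlation 0 lists were called between the times (adjusted p = 0.149 to 0.243 with an estimated correlation for these lists). MT1X fell by 3.93 ± 0.10 on the log2 scale (15.3-fold; limma adjusted p = 3.0e-06) and HSPA5 by 2.02 ± 0.12 (4.06-fold; limma adjusted p = 8.9e-05). CCL2 rose by 3.59 ± 0.15 (limma adjusted p = 2.6e-05) and GADD45G, a growth arrest gene, by 2.98 ± 0.13 (7.89-fold; limma adjusted p = 2.7e-05). Of 9756 genes, 2052 were higher and 1772 lower at 16 than at 8 hours (39.2%), of which 405 and 284 changed at least 2-fold and 23 and 22 at least 4-fold.

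All 8 measured metallothionein and zinc response genes were lower at 16 than at 8 hours (0 higher, 0 not called; 8 lower when adjusted over the list alone). Zinc response genes had a median log2 change of -2.85 (camera adjusted p = 1.1e-09; adjusted p = 0.149 with an estimated correlation). As at 8 hours, near-identical copies in this list may make the camera p-value at the preset correlation too small. MT1G fell by 3.49 ± 0.11 on the log2 scale and SLC30A1 by 1.31 ± 0.15. Of the 38 stress response targets of ATF4, 16 were lower, 4 higher and 18 not called (18 lower and 4 higher when adjusted over the list alone). Targets of ATF4 had a median log2 change of -0.32 (camera adjusted p = 4.0e-04; adjusted p = 0.243 with an estimated correlation). STC2 fell by 1.42 ± 0.14, DDIT3 by 1.32 ± 0.14 and CBS, an enzyme of cysteine synthesis, by 1.28 ± 0.11, whereas ATF3 rose by 0.79 ± 0.12. Of 17 NRF2 targets, 9 were lower, 0 higher and 8 not called (10 lower when adjusted over the list alone). NRF2 targets had a median log2 change of -0.47 (camera adjusted p = 0.00128; adjusted p = 0.161 with an estimated correlation). GCLM, a subunit of the enzyme that starts glutathione synthesis, fell by 1.30 ± 0.10 and TXNRD1, thioredoxin reductase, by 1.08 ± 0.11. Of 3 neuroendocrine markers, 2 were lower, 0 higher and 1 not called (2 lower when adjusted over the list alone). Neuroendocrine markers had a median log2 change of -0.93, or -0.22 with 1 undetected gene at its bound (camera adjusted p = 0.0271; adjusted p = 0.290 with an estimated correlation). TUBB3 fell by 1.46 ± 0.10.

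Of 31 DNA replication genes, 17 were higher at 16 than at 8 hours, 4 lower and 10 not called (19 higher and 4 lower when adjusted over the list alone). Replication genes had a median log2 change of 0.47 (camera adjusted p = 4.0e-04; adjusted p = 0.149 with an estimated correlation). E2F2 rose by 1.83 ± 0.11 on the log2 scale, MCM5, a subunit of the replicative helicase, by 1.58 ± 0.15 and CDT1, which loads that helicase, by 1.44 ± 0.14. Of 19 immediate early genes, 11 were higher, 3 lower and 5 not called (11 higher and 3 lower when adjusted over the list alone). The immediate early genes had a median log2 change of 0.60 (camera adjusted p = 0.00607; adjusted p = 0.213 with an estimated correlation). CCN1 rose by 2.36 ± 0.14 and JUN by 1.33 ± 0.10. Of 14 cytokine response genes, 9 were higher, 1 lower and 4 not called (9 higher and 1 lower when adjusted over the list alone). Cytokine genes had a median log2 change of 0.49 (camera adjusted p = 0.0271; adjusted p = 0.243 with an estimated correlation). NFKBIE, an inhibitor of NF-kappaB, rose by 1.93 ± 0.16, and the member that fell was CXCL8, by 2.10 ± 0.11. Of 18 heat shock genes, 8 were higher, 0 lower and 10 not called (8 higher when adjusted over the list alone). Heat shock genes had a median log2 change of 0.28 (camera adjusted p = 0.0388; adjusted p = 0.243 with an estimated correlation). HSPA1B rose by 1.10 ± 0.10 and HSPH1, a nucleotide exchange factor of chaperones, by 0.75 ± 0.12.

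The call of the heat shock response was lost under median scaling (adjusted p = 0.124, range 0.00704 to 0.124), with the mean of a gene's probes (0.0526) and without 8 hour replicate 2 (0.0753). That of the neuroendocrine markers was lost without a detection filter (median log2 change -0.0058, adjusted p = 0.310, range 0.0220 to 0.310) and with the mean of a gene's probes (0.0684). That of the NF-kappaB and cytokine response was lost among genes detected on all 6 arrays (0.402, range 0.00413 to 0.402). The count of lower genes fell to 1130 without 8 hour replicate 1 and 1144 without 8 hour replicate 2, and the counts of higher and lower genes to 1293 and 1148 without 16 hour replicate 1 and to 1194 and 1088 without 16 hour replicate 2.

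The changes at the treatment times were compared across the 9756 genes. Their log2 changes against control correlated with r = 0.777, where unchanged groups simulated against the same control arrays gave 0.50 on average over 100 simulations (0.482 to 0.532), and their covariance was 0.526 against 0.0106 simulated. The sign was shared by 78.8% of genes (66.6% simulated). Of the called genes, 2173 were higher at both times, where independent lists would share 959, and 1865 were lower at both times, where independent lists would share 762. Genes called in opposite directions were fewer, 66 higher at 8 and lower at 16 hours and 134 the reverse, against 818 and 894 for independent lists. With each time set against a control array of its own, an alternative chosen after seeing the data, r was 0.736 with control replicate 1 for 8 hours and 0.728 with control replicate 2 for 8 hours. The covariance was then 0.510 and 0.508. Each time then had 1 control array, and part of the unsplit r may come from the shared controls. Calls made against the same controls are not independent, so the counts for independent lists are only a reference, and the split was not applied to the shared calls. HSPA5 and STC2 were among the genes higher at 8 hours and lower at 16 hours, with log2 changes of 1.40 and -0.62 for HSPA5 and of 0.58 and -0.84 for STC2, whose rise at 8 hours was not called without control replicate 2 (limma adjusted p = 0.0560) or 8 hour replicate 1 (0.0648).

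**Figure D3:**
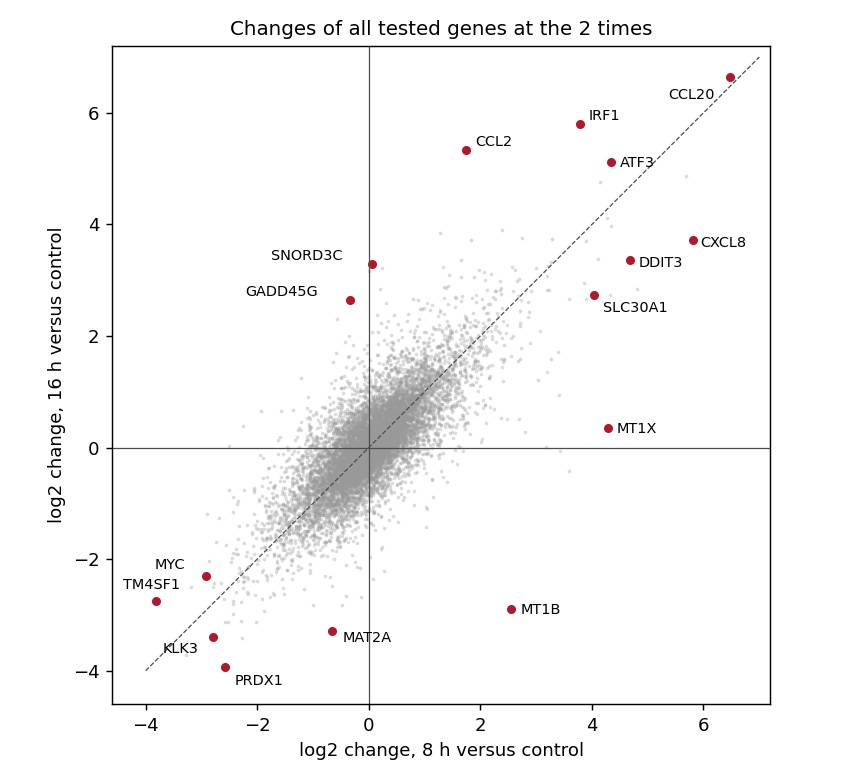
Log2 change at 16 hours (vertical axis) against the log2 change at 8 hours (horizontal axis), both versus control, for each of the 9756 tested genes; the dashed line marks equal change and red points carry gene names. Most points lie along the diagonal (r = 0.777), while MT1X lies right of it (4.29 and 0.36) and CCL2 above it (1.75 and 5.33 as fitted, with control below detection).

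Several genes were reported whatever their test. Both probes of ALOX5 and the probe of ALOX5AP, the target of MK591, failed the detection filter in every group, so neither was tested. The brighter ALOX5 probe lay near the limit, with a detection p of 0.0351 and 0.0286 on the control arrays, and passed the alternative filter of a detection p under 0.05. The ALOX5AP probe had 0.832 and 0.795 on those arrays. MYC remained 2.31 ± 0.12 log2 units below control at 16 hours, a fall of 4.96-fold (limma adjusted p = 1.1e-05), after rising by 0.62 ± 0.12 from its 8 hour level (limma adjusted p = 0.0071, and 0.0507 without 16 hour replicate 2). The list of MYC targets was not called at 16 hours (camera adjusted p = 0.357). Of its 46 genes 19 were lower, 12 higher and 15 not called then, with a median log2 change of -0.06. CCND1, cyclin D1 of the G1 phase, fell by 1.68 ± 0.12 at 8 hours and by 0.97 ± 0.12 at 16 hours (limma adjusted p = 3.7e-05 and 3.2e-04). CDKN1A, the cyclin-dependent kinase inhibitor p21, fell by 0.78 ± 0.13 and by 0.61 ± 0.13 (limma adjusted p = 0.0021 and 0.0060). MCL1, which protects cells from apoptosis, had log2 changes of -0.19 ± 0.15 at 8 hours and 0.38 ± 0.15 at 16 hours on its brighter probe (limma adjusted p = 0.31 and 0.056), while its other probe gave 1.21 and 0.42, so the probes of MCL1 differed in direction at 8 hours. Between the times both MCL1 probes were called, in opposite directions: 0.57 on the brighter probe and -0.80 on the other (limma adjusted p = 0.026 and 0.016 among all passing probes). The MCL1 call on the brighter probe was lost without 8 hour replicate 1 (limma adjusted p = 0.109), 16 hour replicate 1 (0.0868) or 16 hour replicate 2 (0.0889).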

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

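The tests of normalization, probe copies and harvest time in this part were chosen after the results were seen, as was the limit of 4-fold for single genes; the comparison of 16 with 8 hours was fixed in advance. The treatment times differed by the limma test of 16 versus 8 hours for 8 gene lists, of which 0 were called with an estimated correlation (adjusted p = 0.149 to 0.290). Their median log2 changes were -2.85 for metallothioneins and zinc response, -0.93 for neuroendocrine markers (-0.22 with the undetected gene at its bound), -0.47 for NRF2 targets, -0.32 for ATF4 targets, 0.28 for heat shock, 0.47 for DNA replication, 0.49 for NF-kappaB and cytokine response and 0.60 for immediate early genes. Among single genes given in the report, the such log2 changes of at least 4-fold were 3.59 for CCL2, 2.98 for GADD45G, 2.36 for CCN1, 2.02 for IRF1, -2.01 as fitted for TRPM8, undetected at 16 hours, -2.02 for HSPA5, -2.10 for CXCL8, -2.62 for MAT2A, -3.49 for MT1G and -3.93 for MT1X. Of all genes, 66 were called higher at 8 and lower at 16 hours, and 134 the reverse.

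Probes without a gene symbol stood outside the comparisons. Of 3116 that passed the detection filter, limma called 647 higher and 785 lower at 8 hours, and 689 higher and 937 lower at 16 hours. Which transcripts they measure was not analysed here.

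Most of the 9756 genes were called at each time, 57.9% and 60.8%. Quantile normalization of arrays with different signal distributions may create such calls. Under median scaling 91.4% of the 16 hour calls stayed called in the same direction and 2 genes were called in the opposite one, which argues against it as the whole cause. Time in culture or the vehicle cannot be told apart from MK591, because 0 control arrays carry a harvest time and the labels name no vehicle. An effect of the compound itself stays open and was not tested apart from these.

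The metallothionein and zinc response genes were high at 8 hours and lower again at 16 hours. One transcript read by the probes of its near-identical copies could give this pattern among the metallothioneins. The zinc transporters SLC30A1 and SLC30A2, which are no such copies, both rose by at least 4.04 on the log2 scale at 8 hours. As they lie outside this explanation, their rise cannot decide it for the metallothioneins. SLC30A1 was also lower at 16 than at 8 hours, though still above control, and the change of SLC30A2 between the times is not given here. For the single metallothioneins the reading of one transcript by several probes stays open: their rises at 8 hours spanned 2.65 log2 units (1.64 to 4.29), and probes of unequal strength may also give such a span. Quantile normalization was argued against by the 8 of 8 list members called lower at 16 than at 8 hours under median scaling. Because of the near-identical copies, these members may not be 8 separate readings. No biological explanation beyond treatment time was tested.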

How the results depend on the processing

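All alternatives here were fixed before the results were seen, except the split of the control arrays, chosen after seeing the data, which gave a correlation between the times of 0.728 and 0.736. A minimum of 2-fold left 924 higher and 772 lower genes at 8 hours, 1114 and 885 at 16 hours, and 405 and 284 between the times, by construction. With the correlation estimated for each list, 0 lists were called higher and 0 lower in every comparison, while fry, which asks only whether members changed, called 11 higher and 12 lower at 8 hours, 10 and 13 at 16 hours, and 9 and 15 between the times. Camera with an estimated correlation has little power at 3 residual degrees of freedom. Under median scaling 10 lists were lower at 8 hours in place of 6; the cause was not tested. That scaling moved the median log2 change of all genes at 16 hours by -0.13 and turned the balance of calls towards lower genes: 2638 higher and 3152 lower at 8 hours, 2703 and 3337 at 16 hours, and 1818 and 2000 between the times. Leaving out 1 array gave between 1194 and 2123 genes higher and between 1088 and 1854 lower at 16 than at 8 hours; fewer samples carry the test. It gave 2372 to 2805 higher and 2169 to 2572 lower genes at 8 hours, 2618 to 3109 and 2256 to 2678 at 16 hours, and a correlation between the times of 0.768 to 0.788. With a replicate block, 2890 genes were higher and 2682 lower at 8 hours.

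MCL1 reversed with the mean of its probes, which differ in direction, at 8 hours (0.51) and between the times (-0.11). Over the genes given in the report, with 1 array left out 829 values kept direction and side of the threshold, 16 were no longer called and 1 became called. EDEM1 at 16 hours was not called without a detection filter (adjusted p = 0.089), with a detection p under 0.05 (0.0565), with array weights (0.0528), in a fit of only the 4 arrays compared (0.0691) or without any 1 of 5 arrays, and MT1X at 16 hours was not called under median scaling (log2 change 0.06) or without control replicate 1, 16 hour replicate 1 or 16 hour replicate 2 (adjusted p = 0.0574, 0.0592 and 0.0674). Genes near the detection limit are limited by signal over background. Changes of 1.25-fold were not recovered in simulated data. Few genes were changed there, so the adjusted threshold was stricter than in these data, and that recovery does not carry over to them.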

Other observations

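The gene families in this part, the counts among genes detected on all arrays and the test of small nucleolar RNA probes were chosen after the results were seen, while the test of decay factors was chosen before its result was seen. All families were tested with camera over 27 tests, and at the normalization used in the report none passed with an estimated correlation (lowest adjusted p = 0.105). Under median scaling the ZNF genes passed that test at 8 and 16 hours (adjusted p = 0.0248 for both). Directions of the families given here held under median scaling, without background correction and with the authors' processed values, but some sizes did not: without background correction and with the authors' values, medians at 16 hours were 0.56 and 0.42 for the histone genes, -0.74 and -0.62 for the tubulins and 2.29 and 1.99 for the U3 copies. Of 285 genes with symbols starting with ZNF, those of zinc finger proteins with some antisense RNAs and pseudogenes, 167 were higher and 32 lower at 8 hours (58.6% higher against 29.9% of all genes; camera adjusted p = 5.1e-07). The detection filter favours rises here, since 66 of them were detected on no control array; among the 173 detected on all 6 arrays, 89 were higher and 25 lower (51.4% against 28.2% of such genes). Of 17 tubulin genes 14 were lower and 2 higher at 16 hours (median log2 change -1.10; camera adjusted p = 1.7e-04). Of 27 histone genes of the replication type, 17 were higher and 2 lower at 16 hours (median 1.04, camera adjusted p = 2.2e-04), while DNA replication genes were lower. That is 63.0% higher against 32.8% of all genes, though 6 of the histone genes were detected on no control array. Among the 16 detected on all 6 arrays, 10 were higher and 2 lower (62.5% higher against 31.2% of such genes). All 5 measured UGT2B genes, which inactivate steroids, were lower at 16 hours (camera adjusted p = 8.1e-04). Of these 5, 2 were detected on all 6 arrays and 0 were undetected in control, so the detection filter may favour falls. The 5 genes had a median log2 change of -2.16, and of -0.98 with the authors' values. The 3 measured CLK kinases of splicing were higher at 16 hours (camera adjusted p = 0.0095), with a median of 3.18, and of 1.47 with the authors' values.

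Host genes of small nucleolar RNAs, whose spliced transcripts carry these RNAs in introns, were higher in 11 of 14 cases at 8 hours and 12 at 16 hours (camera adjusted p = 7.2e-04 and 1.7e-04), with rises of 2.19 and 3.11 for SNHG12 and 1.66 and 2.63 for SNHG5. Probes reading the small nucleolar RNAs themselves could explain this, which stays open. The 58 probes annotated to small nucleolar RNAs had a median log2 change of -0.54 at 8 hours and -0.40 at 16 hours (-0.20 and -0.18 with the authors' values). The 25 of them detected on all 6 arrays had medians of -0.53 and -0.57. These probes were not matched to the RNAs that the 14 host genes carry, so they cannot decide it. The 3 probes of near-identical copies of the U3 RNA were an exception: 0 were called at 8 hours, but all were higher at 16 hours (median log2 change 3.22; camera adjusted p = 0.0034; adjusted p = 0.138 with an estimated correlation). Less nonsense-mediated decay, which degrades many host transcripts, is a candidate explanation that stays open: 4 transcripts of decay factors that this pathway itself degrades had a median log2 change of 0.51 at 8 hours, with 3 higher, and of 0.28 at 16 hours, with 1 higher (0.35 and 0.17 with the authors' values). The camera test of these transcripts passed no threshold at either time (adjusted p = 0.331 and 0.396). Between the times their median changed by -0.06 and that of the host genes by 0.61 (0.40 under median scaling).

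Where genes had over 1 passing probe, 51, 53 and 22 of 2454 had probes called in opposite directions in the 3 comparisons. At 16 hours 4 genes, HNRNPA2B1, PPM1A, SPTLC1 and ZBTB8OS, had such probes that each changed at least 2-fold.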
